A study of Bacillus subtilis with 3 samples.

How the data were processed

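The series holds 3 two-colour arrays of Bacillus subtilis RNA, each with TEK1 in one channel and PY79 in the other. Per the labels, channel A is Cy3 and channel B is Cy5, the strains' dyes were exchanged on 1 array, and RNA came from 3 replicate cultures. Per the labels' protocols, total RNA was reverse transcribed with random nonamers and aminoallyl dUTP, and the cDNA was coupled to Cy3 or Cy5. The deposited scanner files hold spot intensity values, as raw brightness, local background and net brightness of each channel, with a second background value per print grid, per the file headers. In the files net brightness equals raw minus background and is 0 where that is negative. 400 to 420 of all spots per channel were blanked on each array, and 5.36% to 7.20% of gene spots were blanked in at least 1 channel. The scanner software, its settings and the authors' normalisation are not given in the sources used here. The deposited value table holds natural log ratios, which was worked out from the values: its columns correlated at r = 0.951, 0.975 and 0.987 with ratios recomputed from the second net brightness with a loess within each grid and turned to TEK1 over PY79, and their SD was 0.732, 0.687 and 0.693 times that of the recomputed log2 ratios. The medians of its columns are -0.00706, 0.00109 and -0.00711, and it has no value for 128, 29 and 17 genes. Its direction and its centring within grids were inferred in the same way and stay unstated in the labels.

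All steps below were computed from the scanner files with R 4.3.3 and limma 3.58.1. Background was corrected with normexp at an offset of 50 on raw minus background. Blanked spots were left out. Log2 ratios were normalised within each array with a loess curve of span 0.3, with 1 curve per array as the setting fixed before the data were examined. A separate curve for each of the 36 print grids was among the alternatives fixed at that time and is reported beside it. The alternatives run on the per-grid ratios and the naming of genes from that fit were chosen after seeing the data. Control spots had no weight in the curves. Ratios were turned to TEK1 over PY79, the 2 spots of a gene were averaged, and 3816 of 4106 genes with a ratio on the 3 arrays were tested with lmFit and eBayes against 0, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit leaves 2 residual degrees of freedom. A gene counted as above background on an array where the mean net brightness of its spots passed the 95th percentile of the 46 luc control spots of that channel. Empty spots, of which there are 114, were not used for this since some were bright.

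Gene names come from the array and were updated by locus tag with the RefSeq gene table of assembly ASM904v1. 4038 of 4106 probes matched, and 1028 carry another name there. That table was used for names only. A list member was matched by its name on the array first and by its updated name otherwise. This matching was corrected after the results were seen, because updated names had drawn other genes into some lists, the matrix and sigma-K lists among them. The members as written were not changed, and the same lists were called before and after the correction. The build behind the array is not given in the sources used here, so no coordinates are printed.

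Genes were named by a rule fixed before the data were examined. It takes yvfI and its neighbours, the 15 genes with the largest rise and the 15 with the largest fall among those past the threshold with the same sign on 3 arrays, and, where under 10 pass in a direction, the lowest p values up to 10. It adds up to 4 members with the largest mean ratio of each called list and of the bacilysin list. Applied to both fits, it named 125 genes. Exceptions are said to be named after their values were seen. The 36 gene lists were fixed before the data were examined, need at least 4 measured genes and were tested with limma's camera at a preset correlation of 0.01. Camera with an estimated correlation and fry were alternatives.

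The other alternatives were no background subtraction, plain subtraction, median centring, scaling between arrays, a dye term that leaves 1 residual degree of freedom, a limit to the 3348 genes above background in at least 1 channel on 3 arrays, blanked spots kept, each replicate left out in turn, replicates 1 and 3 averaged as if they were 1 culture, since their slide names share a number and leave open a single culture hybridised in both dye orientations, duplicate spots kept with duplicateCorrelation, trended and robust eBayes, lists of at least 8 genes, and the deposited value table. The closing section gives their effect. The tables of lists and lut genes with a replicate left out were added after seeing the data.

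The steps were tested on simulated data made from these arrays, with 3816 genes tested and the measured grid differences added. With 1 curve per array, 41.0% of 100 genes changed by a log2 ratio of 1 and 98.0% of 100 genes changed by 2 were recovered, with 0 false calls among 3596 unchanged genes. With a curve per grid 98.0% and 100% were recovered, with 6 false calls. The median absolute log2 ratios came out at 0.87 for genes changed by 1 and 1.73 for genes changed by 2. In this simulation the per-grid steps thus shrank the ratios. Without the grid differences, a run added after seeing the data, 1 curve per array recovered 98.0% and 100% with 9 false calls, and a curve per grid 98.0% and 100% with 7. A planted list was found in both fits and 0 of 36 unchanged lists were called. These lists held randomly drawn genes with independent noise, so this does not test lists whose genes vary together. The ratio noise was drawn with the same SD for every gene, the median SD of the per-grid fit. The recovery therefore does not carry over to measured genes, whose spread is uneven. The p-values of single genes measure the spread between 3 arrays, counted as 3 cultures as the design text says. The 2 dye orientations are not balanced. The p-values of lists at the preset correlation compare a list's genes with all other genes. Their small size rests on the number of genes and on the assumed correlation, and does not measure the spread between cultures.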

Results

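Gene expression was compared between TEK1, a yvfI mutant of Bacillus subtilis, and its parent PY79, a laboratory wild-type strain. Both strains were grown in PA medium to an optical density of 7. Total RNA of the strains was labelled with the fluorescent dyes Cy3 and Cy5 and hybridised together on each of 3 spotted arrays, which the series' design text describes as biological replicates. TEK1 carried Cy3 in replicate 1 and Cy5 in replicates 2 and 3. Each array held 8448 spots in 36 print grids, with 4106 gene probes spotted 2 times. The median net spot brightness was 629 in Cy3 and 332 in Cy5 on replicate 1, 454 and 359 on replicate 2, and 547 and 644 on replicate 3. Duplicate spots of a gene correlated across genes at r = 0.974, 0.923 and 0.980 on the 3 arrays. Gene probes brighter than the 95th percentile of the luc control spots made up 91.4%, 64.2% and 76.8% in Cy3, and 89.6%, 83.8% and 83.5% in Cy5. As a background measure, 182 probes for the SPβ prophage, a phage that PY79 lacks, had median net brightness of 21.0, 40.9 and 33.4 in Cy3. Of these probes 31.3%, 26.4% and 19.2% passed the same limit in at least 1 channel, so dim genes that pass it can still carry unspecific signal. The number of arrays limits the precision of every ratio below.

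The targeted gene was examined first. yvfI (locus BSU34180), now named lutR, codes for a transcription factor of the GntR family known as a repressor of the lactate utilisation operon lutABC. Its probe had a log2 ratio of TEK1 over PY79 of -1.46, -0.91 and -0.46 on replicates 1 to 3 when each print grid was normalised separately, so lutR fell by 0.94 ± 0.50 (SD, n = 3, adjusted p = 0.0401). With 1 normalisation curve per array its log2 ratio was -1.29 ± 0.71 with an adjusted p of 0.246. The probe stayed above background in TEK1 on 3 arrays, with a mean net brightness of 1231 against 3299 in PY79. The labels do not say where in the gene the mutation lies, so the probe checks the strain labels only in part. The operon that LutR is known to repress did not pass the test with all 3 arrays in either fit. In the per-grid fit lutA had a log2 ratio of 0.25 ± 0.24 (adjusted p = 0.214), lutB of 0.33 ± 0.43 (adjusted p = 0.248) and lutC of 0.33 ± 0.24 (adjusted p = 0.125). The lactate permease gene lutP, next to lutR, had -0.24 ± 0.29 (adjusted p = 0.269). Without replicate 1, on the 2 arrays with TEK1 in Cy5, lutA, lutB and lutC passed in both fits, with log2 ratios of 0.38, 0.57 and 0.46 per grid (adjusted p from 0.00709 to 0.0182) and 1.35, 1.23 and 0.94 with 1 curve per array (adjusted p from 0.00635 to 0.00852). Strain and dye cannot be separated on these 2 arrays. There 2102 genes in all passed with 1 curve per array and 1657 per grid. With 1 curve per array the log2 ratios of lutA, lutB and lutC on replicate 1 had the opposite sign, at -0.64, -0.83 and -1.11. Without replicate 1 lutP also passed with 1 curve per array, at -0.85 (adjusted p = 0.00930), and not per grid.

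The comparison of TEK1 with PY79 asks which genes depend on YvfI. In the fit with print grids normalised separately, 14 of 20 bacillaene and plipastatin genes, 14 of 19 biofilm matrix genes, 36 of 52 ribosomal protein genes and 17 of 24 genes of ATP synthase and respiration rose in TEK1, and 0 of these fell. The polyketide synthase gene pksL (locus BSU17190) rose 10.4-fold, with a log2 ratio of 3.37 ± 0.45 (SD, n = 3). bslA (locus BSU31080, yuaB on the array), which codes for the hydrophobic coat protein of biofilms, rose 7.68-fold, with a log2 ratio of 2.94 ± 0.12. Both were above background in PY79 on 2 of the 3 arrays, and their PY79 signal stayed under the background limit on the other array. All 9 arginine synthesis genes, 14 of 23 aromatic amino acid and histidine genes, 16 of 33 genes of the cell envelope stress response and 14 of 42 forespore genes fell. aprE (locus BSU10300), which codes for the extracellular protease subtilisin, fell 4.60-fold, with a log2 ratio of -2.20 ± 0.10.

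How many genes passed depended on the normalisation. With 1 loess curve per array, the setting fixed before the data were examined, limma called 0 of 3816 genes at an adjusted p under 0.05. The lowest adjusted p was 0.0984, and 467 genes had an unadjusted p under 0.05. With a loess curve for each print grid, an alternative also fixed in advance, 793 genes passed, of which 480 rose and 313 fell. All 793 had the same sign on the 3 arrays, and 785 of them (99.0%) had the same sign in the whole-array fit. Of the 467 genes at an unadjusted p under 0.05 in the whole-array fit, 375 were called in the per-grid fit with the same sign. At least 2-fold changes were found for 187 of the called genes, 133 up and 54 down. The per-grid count was 1657 without replicate 1, 254 without replicate 2 and 0 without replicate 3. The whole-array count was 2102, 55 and 2 in the same order, and 1006 with all arrays and a dye term. Below, rose and fell refer to the per-grid fit.

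**Figure D1:**
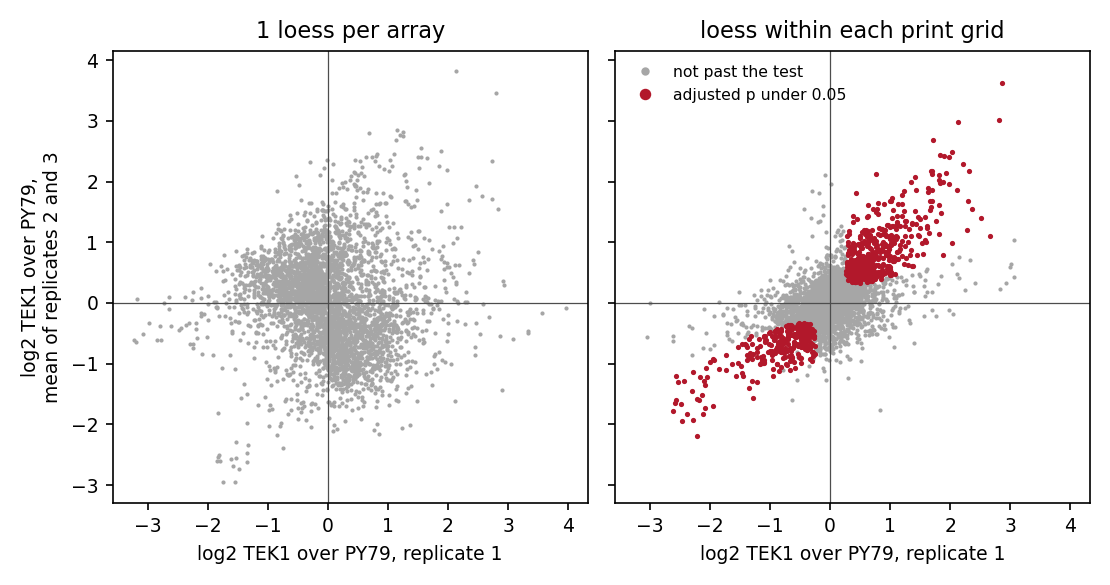
Log2 ratios of TEK1 over PY79 of each tested gene on replicate 1 (horizontal axis, TEK1 in Cy3) against the mean of replicates 2 and 3 (vertical axis, TEK1 in Cy5), with 1 loess per array on the left and a loess within each print grid on the right. Red points mark the 793 genes at an adjusted p under 0.05 on the right, and no point on the left passes.

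The 3 arrays differed in how well they matched. With 1 loess per array, ratios turned to TEK1 over PY79 correlated across genes at r = -0.13 between replicates 1 and 2, 0.07 between replicates 1 and 3, and 0.90 between replicates 2 and 3. The per-grid fit gave r = 0.56, 0.67 and 0.87. Spearman correlations were -0.25, -0.09 and 0.91 with 1 loess per array, and 0.50, 0.62 and 0.83 per grid. Genes are not independent replicates, so no p is given. Replicates 2 and 3 share a dye orientation and replicate 1 has the opposite one, so a difference of replicate 1 from the others cannot be separated from its dye orientation. Median Cy5 over Cy3 ratios of the 36 print grids, left unturned, correlated at r = 0.92 between replicates 1 and 2 and 0.89 between replicates 1 and 3. The grid explained 28.6%, 59.2% and 42.2% of the variance of the ratios on replicates 1 to 3.

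**Figure D2:**
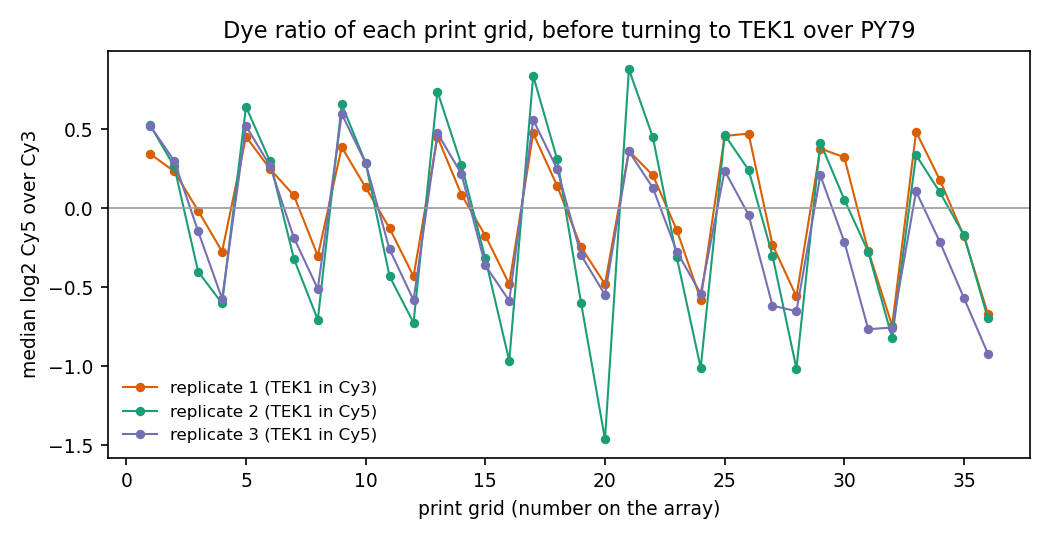
Median log2 ratio of Cy5 over Cy3 (vertical axis) of each of the 36 print grids (horizontal axis, grid number) on the 3 arrays, not turned to TEK1 over PY79. The arrays follow one another across the grids although the strains' dyes were exchanged on replicate 1, with r = 0.92 and 0.89 against replicates 2 and 3.

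The 15 largest rises in the per-grid fit were led by pksL and bslA and included other polyketide genes and genes of fatty acid synthesis. pksN, pksJ and pksR, of the same bacillaene synthase cluster as pksL, rose by log2 ratios of 2.27 ± 0.25, 2.23 ± 0.37 and 2.02 ± 0.36. fabHB, which starts fatty acid chains, rose 6.50-fold (2.70 ± 0.50), fabD, which loads malonyl units, rose by 2.36 ± 0.56, and fabG and the acyl carrier protein gene acpA rose by 2.25 ± 0.32 and 2.27 ± 0.30. The ribonuclease III gene rnc, next to acpA, rose by 2.33 ± 0.33. The plipastatin synthetase gene ppsE rose by 2.07 ± 0.12, the pyrimidine regulator gene pyrR by 2.22 ± 0.15, the cell wall hydrolase gene cwlO by 2.01 ± 0.32, the signal peptidase gene sipW by 2.01 ± 0.17 and sdpB, needed to mature a cannibalism toxin, by 1.98 ± 0.26. All 15 had adjusted p from 0.00433 to 0.00778. In PY79, pksL, pksN, pksJ, pksR, ppsE, bslA and pyrR were above background on 2 of the 3 arrays.

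The 15 largest falls were mostly genes of amino acid synthesis and proteases. carA and carB, the arginine-regulated carbamoyl phosphate synthase, fell by 2.11 ± 0.36 and 2.02 ± 0.41 on the log2 scale. The arginine genes argD, argF, argH, argB and argJ fell with log2 ratios of -2.05 ± 0.50, -2.04 ± 0.21, -1.94 ± 0.47, -1.84 ± 0.20 and -1.79 ± 0.37, and the tryptophan genes trpD, trpC and trpF with -1.95 ± 0.65, -1.93 ± 0.33 and -1.92 ± 0.71. The intracellular protease gene ispA fell by 1.78 ± 0.20 beside aprE. liaH, a phage shock protein homologue induced by envelope damage, fell by 1.79 ± 0.37, yceF by 1.73 ± 0.51, and refZ, a regulator of cell division during sporulation, by 1.73 ± 0.36. Adjusted p ran from 0.00433 to 0.0174.

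**Figure D3:**
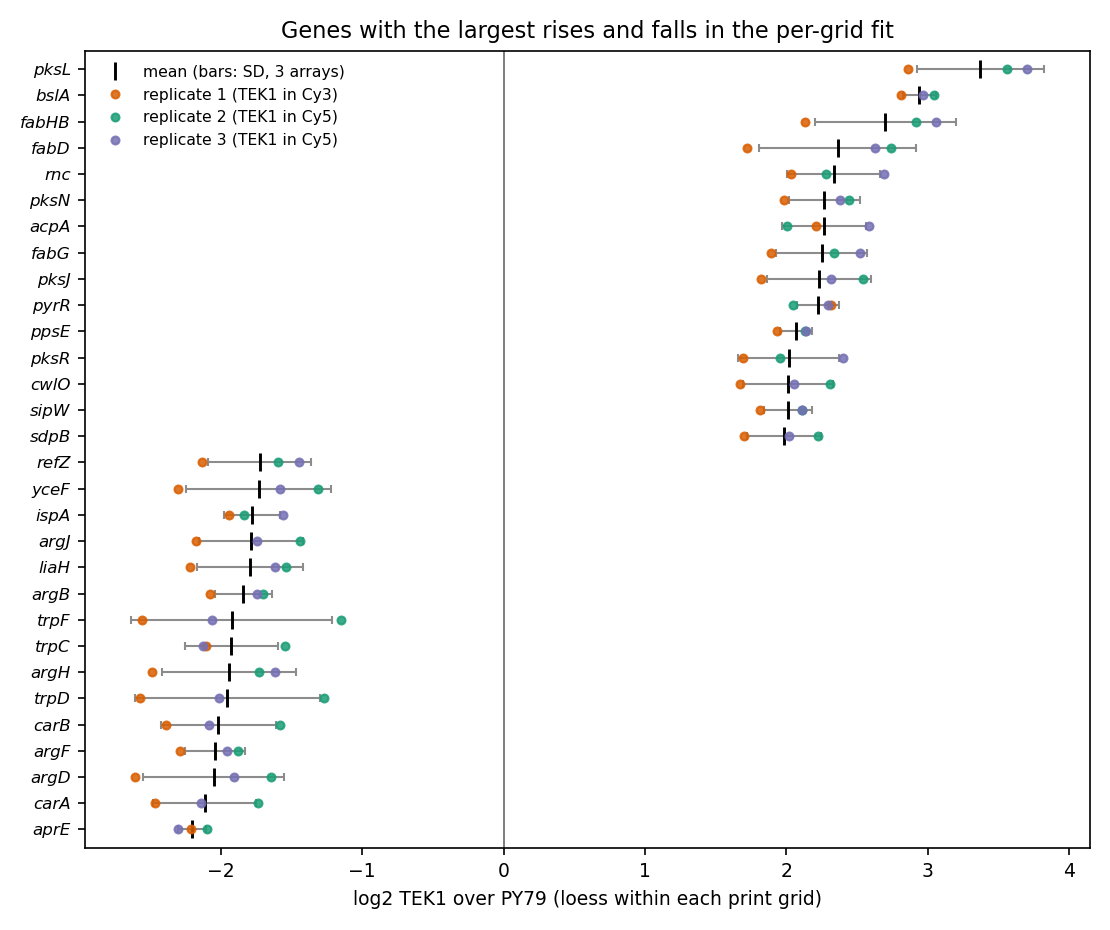
Log2 ratio of TEK1 over PY79 in the per-grid fit (horizontal axis) of the 15 genes with the largest rises and the 15 with the largest falls (vertical axis). Coloured points are the 3 arrays, black ticks their mean and bars the SD. Each gene has the same sign on the 3 arrays, from pksL at 3.37 to aprE at -2.20.

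In the whole-array fit, where no gene passed, the 20 genes with the lowest p and the same sign on 3 arrays had an adjusted p of 0.0984. Among them pksL had a log2 ratio of 3.24 ± 0.40, bslA 3.25 ± 0.99, fabHB 2.47 ± 0.32, pyrR 2.30 ± 0.37, pksN 2.12 ± 0.20, pksJ 2.12 ± 0.27, fabD 2.11 ± 0.31, ppsE 2.13 ± 0.49, pksR 1.88 ± 0.35 and walM 2.15 ± 0.43. On the negative side argD had -2.31 ± 0.41, carA -2.33 ± 0.48, carB -2.25 ± 0.57, argF -2.31 ± 0.65, argB -2.21 ± 0.59, argJ -2.03 ± 0.44, trpD -2.27 ± 0.41, trpE -2.36 ± 0.45, trpF -2.55 ± 0.71 and refZ -1.81 ± 0.06.

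The 36 gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01. The whole-array fit called 20 lists, 12 up and 8 down, and the per-grid fit 15, 9 up and 6 down, all 15 among the 20 and in the same direction. With an estimated correlation no list passed in either fit, where fry called 2 lists in the whole-array fit and 5 in the per-grid fit. Camera with an estimated correlation rests on the 2 residual degrees of freedom, so it had little power. Per grid it gave an adjusted p of 0.595 to arginine synthesis and to iron limitation alike. Its adjusted p values therefore neither back nor weaken the call of a single list. The array signs turned so that they followed the dye in place of the strain gave 19 called lists in the per-grid fit. The counts of members in the gene test depend on single arrays, with 48, 19 and 0 ribosomal protein genes that rose per grid and 33, 1 and 0 forespore genes that fell without replicates 1, 2 and 3 in turn. Without replicate 1 the whole-array calls of the biofilm matrix, forespore and late mother-cell lists ended (adjusted p = 0.188, 0.0558 and 0.176), with medians of 0.26, -0.11 and 0.23 against 0.55, -0.35 and 0.52 with all arrays.

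**Figure D4:**
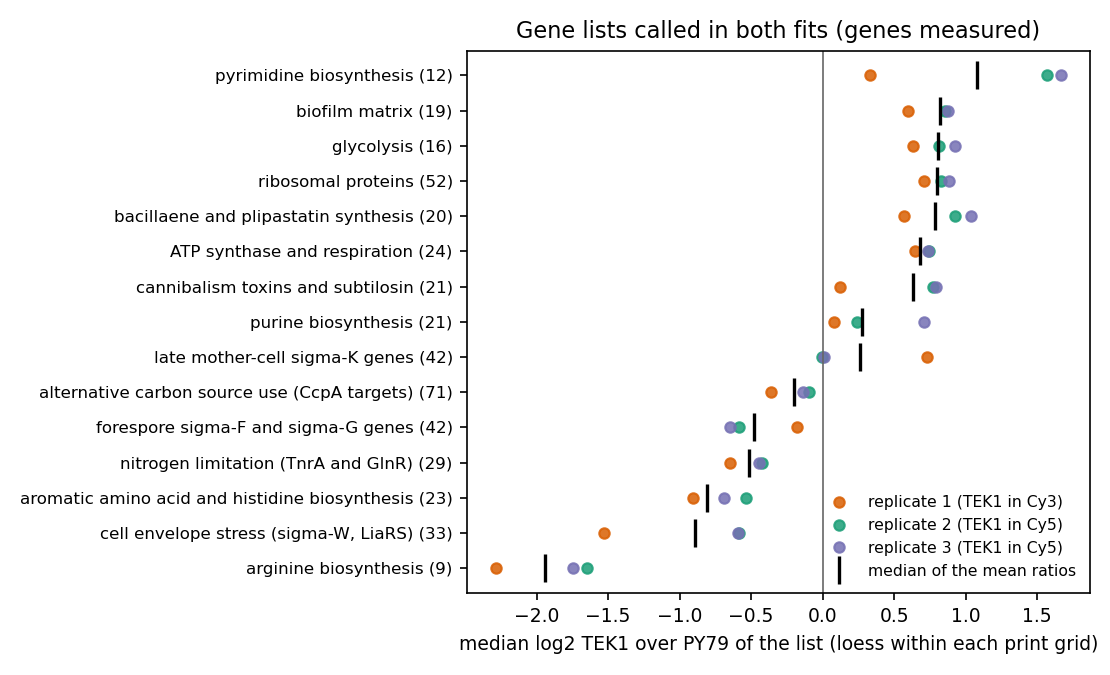
Median log2 ratio of TEK1 over PY79 (horizontal axis) of the 15 gene lists called in both fits (vertical axis, with the number of genes measured), from the per-grid fit. Coloured points are the 3 arrays and black ticks the median of the mean ratios, from 1.08 for pyrimidine biosynthesis to -1.94 for arginine biosynthesis.

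The lists of bacillaene and plipastatin, of the biofilm matrix and of cannibalism toxins were called up in TEK1. Of 20 measured bacillaene and plipastatin genes 14 rose and 0 fell over all genes, and 15 rose when adjusted over the list alone, with a list median of 0.79 (adjusted p = 1.06e-08, and adjusted p = 0.595 with an estimated correlation). Of 19 matrix genes 14 rose and 0 fell, and 17 rose adjusted over the list alone, with a median of 0.82 (adjusted p = 8.17e-09, and adjusted p = 0.595 with an estimated correlation). Besides bslA and sipW, tasA, the main matrix fibre protein, rose by 1.35 ± 0.84 (adjusted p = 0.0499), and epsA, first gene of the exopolysaccharide operon, by 0.97 ± 0.06. 4 other called eps genes, epsD, epsE, epsG and epsO, named after their values were seen, were not well above background in PY79 on any array, and no fold is given for them. Of 21 genes for cannibalism toxins and subtilosin 7 rose and 1 fell, and 10 rose and 3 fell adjusted over the list alone, with a median of 0.63 (adjusted p = 0.00471, and adjusted p = 0.702 with an estimated correlation). sdpA rose by 1.17 ± 0.27, and skfE and skfF, the exporter of the killing factor, by 0.83 ± 0.11 and 0.87 ± 0.09. The gene that fell, named after its value was seen, was the repressor gene sdpR (log2 ratio -0.59). Among the 13 genes that passed in neither direction, also named after their values were seen, skfA had -0.33, sboA -0.26 and spbC 0.61. The median of this list was 0.12, 0.77 and 0.79 on replicates 1 to 3.

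The lists of ribosomal proteins, of ATP synthase and respiration and of glycolysis were called up in TEK1. Of 52 ribosomal protein genes 36 rose and 0 fell, and 48 rose adjusted over the list alone, with a median of 0.80 (adjusted p = 4.57e-17, and adjusted p = 0.595 with an estimated correlation). In the whole-array fit their median was 1.42, with 0 that passed over all genes and 36 that rose adjusted over the list alone. rplJ rose by 1.71 ± 0.26, rplL by 1.69 ± 0.15, rpsD by 1.58 ± 0.10 and rpsB by 1.38 ± 0.46. Of 24 genes of ATP synthase and respiration 17 rose and 0 fell, and 18 rose adjusted over the list alone, with a median of 0.68 (adjusted p = 6.56e-10, and adjusted p = 0.595 with an estimated correlation). The ATP synthase genes atpF, atpE, atpA and atpG rose by 1.96 ± 0.05, 1.95 ± 0.14, 1.95 ± 0.11 and 1.85 ± 0.38. Of 16 glycolysis genes 11 rose and 0 fell, and 12 rose adjusted over the list alone, with a median of 0.81 (adjusted p = 1.66e-07, and adjusted p = 0.595 with an estimated correlation). tpiA rose by 1.67 ± 0.07, pgm by 1.47 ± 0.10, gapA by 1.38 ± 0.23 and pgk by 1.32 ± 0.07.

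Both nucleotide synthesis lists were called up in TEK1, with 6 of 12 pyrimidine genes and 16 of 21 purine genes that passed in neither direction. Of 12 pyrimidine genes 6 rose and 0 fell, the same counts as adjusted over the list alone, with a median of 1.08 (adjusted p = 2.20e-05, and adjusted p = 0.595 with an estimated correlation). The median was 0.33, 1.57 and 1.67 on replicates 1 to 3. pyrAA rose by 1.67 ± 0.83 and the UMP kinase gene pyrH by 1.49 ± 0.13, while pyrAB had 1.37 ± 1.26 and did not pass. In PY79 pyrAA and pyrAB were above background on 1 array. Of 21 purine genes 5 rose and 0 fell, and 8 rose and 2 fell adjusted over the list alone, with a median of 0.27 (adjusted p = 0.0409, and adjusted p = 0.794 with an estimated correlation). The call ended without replicate 3 (median 0.19, adjusted p = 0.137), and in the whole-array fit without any 1 of the 3 (adjusted p from 0.0952 to 0.202), where the median stayed at 0.34, 0.27 and 0.31 against 0.39 with all arrays. purS, purL and purC, of the inosine monophosphate pathway, rose by 1.02 ± 0.56, 0.90 ± 0.51 and 0.83 ± 0.48, where the whole-array fit gave purS 0.64 and purC 0.54 (adjusted p = 0.405 and 0.488).

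The lists of arginine synthesis, of aromatic amino acid and histidine synthesis and of nitrogen limitation were called down in TEK1, while that of cysteine and methionine synthesis did not pass. All 9 arginine genes fell, also adjusted over the list alone, with a median of -1.94 (adjusted p = 8.69e-08, and adjusted p = 0.595 with an estimated correlation). Of 23 aromatic amino acid and histidine genes 14 fell and 3 rose, and 17 fell and 3 rose adjusted over the list alone, with a median of -0.81 (adjusted p = 8.65e-06, and adjusted p = 0.595 with an estimated correlation). trpE fell by 1.71 ± 0.87. The 3 that rose, named after their values were seen, were aroA (aroE on the array), pheA and tyrA with log2 ratios of 0.51, 0.67 and 0.44, which serve the common pathway or phenylalanine and tyrosine. Of 29 genes of nitrogen limitation 9 fell and 0 rose, and 10 fell adjusted over the list alone, with a median of -0.51 (adjusted p = 1.47e-05, and adjusted p = 0.595 with an estimated correlation). The glutamine transport genes glnM and glnP fell by 0.79 ± 0.18 and 0.82 ± 0.38, and glnM had -1.38 in the whole-array fit (adjusted p = 0.405). The glutamate synthase genes gltA and gltB had log2 ratios of -1.29 ± 1.16 and -1.39 ± 1.44 and did not pass, nor did glnA with -1.24 ± 1.19 and glnR with -1.17 ± 0.76. On replicate 1 gltA, gltB and glnA had -2.62, -3.04 and -2.62, against -0.42 to -0.75 on replicates 2 and 3.

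The lists of the cell envelope stress response and of alternative carbon sources were called down in TEK1, the second with 55 of 71 genes that passed in neither direction. Of 33 genes under sigma-W or the LiaRS system 16 fell and 0 rose, and 24 fell adjusted over the list alone, with a median of -0.90 (adjusted p = 3.00e-09, and adjusted p = 0.595 with an estimated correlation). The median was -1.53, -0.58 and -0.59 on replicates 1 to 3, and -0.58 without replicate 1 (adjusted p = 1.42e-09). liaI fell by 1.59 ± 0.42, and nfeDB (yuaF on the array) and the flotillin gene floT of the same operon by 1.67 ± 0.67 and 1.26 ± 0.59. Of 71 genes for carbon sources under catabolite control 14 fell and 2 rose, the same counts as adjusted over the list alone, with a median of -0.20 (adjusted p = 7.36e-04, and adjusted p = 0.741 with an estimated correlation). The median was -0.36, -0.10 and -0.14 on replicates 1 to 3, and -0.13 without replicate 1 (adjusted p = 0.0327). In the whole-array fit it was -0.39, with 0 genes that passed. The acetoin dehydrogenase genes acoB, acoA, acoC and acoL fell by 1.31 ± 0.39, 1.27 ± 0.64, 1.25 ± 0.22 and 1.15 ± 0.51. The 2 that rose, named after their values were seen, were acuB and acuC of acetoin use, with log2 ratios of 0.46 and 0.37.

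Of 42 forespore genes under sigma-F or sigma-G 14 fell and 0 rose, and 18 fell adjusted over the list alone, with a median of -0.48 (adjusted p = 3.82e-08, and adjusted p = 0.595 with an estimated correlation). The small acid-soluble protein gene sspH fell by 1.06 ± 0.12, the germination receptor gene gerKA by 0.73 ± 0.40 and the germination protease gene gpr by 0.56 ± 0.13, while sspC had -0.90 ± 1.58 and gerKC -0.76 ± 0.52 and neither passed. In the whole-array fit sspH had -0.31 (adjusted p = 0.785), and 0.23 without replicate 1. Of 42 late mother-cell genes under sigma-K 6 rose and 1 fell, and 0 passed adjusted over the list alone, with a median of 0.26 (adjusted p = 0.0297, and adjusted p = 0.838 with an estimated correlation). The median of this list was 0.73 on replicate 1 and -0.0050 and 0.0090 on replicates 2 and 3. Its whole-array value was 0.52, with 0 genes that passed. Without replicate 1 the per-grid median turned to -0.05 and the call ended (adjusted p = 0.828), and it was 0.40 and 0.39 without replicates 2 and 3. The spore polysaccharide gene spsI rose by 0.68 ± 0.36, while the crust genes cgeB, cgeA and cgeC had 1.72 ± 1.18, 1.44 ± 1.37 and 1.22 ± 0.95 and the coat gene cotG 1.20 ± 1.50, and none of these 4 passed. On replicate 1 these 4 had 3.07, 3.01, 2.15 and 2.94, against 0.26 to 1.26 on replicates 2 and 3. The 1 that fell, named after its value was seen, was gerPA (log2 ratio -0.40). The 35 mother-cell genes under sigma-E did not pass as a list (median -0.09 and adjusted p = 0.139 per grid, median 0.12, mean -0.02 and adjusted p = 0.867 in the whole-array fit), with 5 that fell and 1 that rose.

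Genes for bacilysin, an antibiotic dipeptide, did not pass as a list (median -0.11 and adjusted p = 0.508 per grid, median -0.0036, mean 0.12 and adjusted p = 0.705 in the whole-array fit). Of its 7 genes bacD rose by 0.42 ± 0.07 and bacA fell by 0.50 ± 0.12, while bacC had 0.10 ± 0.27 and bacE -0.02 ± 0.31. The whole-array value of bacA was -0.30 (adjusted p = 0.771), and 0.17 without replicate 1. In PY79 bacA, bacC and bacD were above background on 1 array. The 5 surfactin genes had a median of 0.16 (adjusted p = 0.424), and 0 passed. 5 lists passed in the whole-array fit alone, and each of these calls ended with 1 replicate left out, though not each median shrank. Fatty acid synthesis and degradation had a median of 0.54 without replicate 1 (adjusted p = 0.281), fermentation 0.32 and 0.47 without replicates 2 and 3 in turn (adjusted p = 0.269 and 0.171), teichoic acid synthesis 0.22 without replicate 2 (adjusted p = 0.163), general stress -0.37 and -0.14 without replicates 1 and 2 in turn (adjusted p = 0.0702 and 0.0952) and iron limitation -0.14 without replicate 2 (adjusted p = 0.0941). Fatty acid synthesis and degradation had a whole-array median of 0.35 (adjusted p = 0.0112, and adjusted p = 0.398 with an estimated correlation) and a per-grid median of 0.24 (adjusted p = 0.136). Per grid 11 of its 26 genes rose, fabHB, fabD, acpA and fabG among them, and 4 fell, and 11 rose and 6 fell adjusted over the list alone. The 4 that fell, named after their values were seen, were fadN, mmgA, mmgB and mmgC, with log2 ratios of -0.54, -0.65, -0.81 and -0.97, which serve fatty acid breakdown or the methylcitrate pathway. Fermentation and anaerobic respiration had a whole-array median of 0.45, with -0.15 on replicate 1 (adjusted p = 0.0232, and adjusted p = 0.398 with an estimated correlation). Per grid 10 of its 23 genes rose, such as the nitrite exporter gene narK by 0.95 ± 0.11 and the lactate dehydrogenase gene lctE by 0.53 ± 0.15, and 4 fell, nasD, nasE and nasF of the nitrite reductase operon by 0.95 ± 0.16, 1.04 ± 0.10 and 1.04 ± 0.09 and the flavohaemoglobin gene hmpA by 0.64 ± 0.29. In the whole-array fit nasD, nasE and nasF had -0.44, -0.53 and -0.44 (adjusted p from 0.579 to 0.669), with nasD at 0.081 and nasF at 0.075 without replicate 1, and lctE had 0.82 (adjusted p = 0.282). Per grid 13 rose and 6 fell adjusted over the list alone. Teichoic acid synthesis had a whole-array median of 0.53, with -0.31 on replicate 1 (adjusted p = 0.00201, and adjusted p = 0.631 with an estimated correlation), and 0 of its 15 genes passed per grid, with dltB at 1.31 ± 1.13. The general stress regulon had -0.23 (adjusted p = 0.0221, and adjusted p = 0.463 with an estimated correlation), and per grid 7 of its 44 genes fell, such as gsiB by 0.77 ± 0.33 and ctc by 0.64 ± 0.23, and 3 rose, gtaB by 0.67 ± 0.28 among them. 9 fell and 3 rose adjusted over the list alone. The iron limitation list had -0.37, with 0.06 on replicate 1 (adjusted p = 0.00122, and adjusted p = 0.483 with an estimated correlation), and per grid 2 of its 31 genes fell, the iron uptake genes fhuD by 0.69 ± 0.22 and fecE by 0.49 ± 0.06, the same 2 counted adjusted over the list alone.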

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

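The signals below appeared in control spots, which no comparison uses, and no biological explanation was tested for them. The probe for a kanamycin resistance gene of a plasmid, a sequence foreign to these strains as far as the labels say, exceeded the luc control limit in both channels on the 3 arrays, with a mean net brightness of 550 in TEK1 and 1030 in PY79. On replicates 1 to 3 it was 192, 931 and 526 in TEK1 and 109, 2180 and 805 in PY79, so the Cy3 channel was the brighter one on each array and the strain means give no direction. The probe for lacZ did the same, with means of 467 in TEK1 and 826 in PY79 and with 201, 513 and 687 in TEK1 and 97.1, 1180 and 1200 in PY79 on replicates 1 to 3, again brighter in Cy3 on each array. Among the 114 spots listed as empty, 6 were brighter than every luc control spot in both channels on the 3 arrays, with mean net brightness from 1885 to 2479, in 2 print grids and 1 grid column.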

How the results depend on the processing

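The whole-array fit called 0 genes, also without background subtraction, with plain subtraction, median centring, scaling, the limit to genes above background, blanked spots kept, and trended and robust eBayes. It called 793 genes with a loess per grid, 1006 with a dye term, 235 with replicates 1 and 3 as 1 culture, 609 from the deposited value table, 106 with duplicateCorrelation and 2 to 2102 when 1 replicate was left out. The deposited table was inferred to be centred within grids, and its count stands as an alternative to both fits. Of its 609 genes 565 were among the 793. The per-grid count of 793, whose alternatives were chosen after seeing the data, was 1878 with a dye term, which kept the 793 genes, 0 to 1657 with 1 replicate left out, and 609 to 1184 otherwise. In the self-test, grid differences lowered the whole-array recovery of genes changed by 1 to 41.0% from 98.0%. For genes changed by 2 the recovery was 98.0% with grid differences and 100% without. On the measured arrays the whole-array fit called 0 genes, though pksL had a log2 ratio of 3.24 and bslA of 3.25. Why genes with such ratios did not pass was not tested, nor were the causes of the other differences. Lists called were 0 in both fits with an estimated correlation, 2 (whole-array) and 5 (per-grid) with fry, 15 to 21 and 14 to 18 under the other settings, 16 to 19 and 15 to 19 with 1 replicate left out. The mean correlation between arrays was -0.13 to 0.90 with 1 replicate left out, against 0.28.

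Of the 125 named genes' whole-array values 1106 kept their direction and side of the threshold over the alternatives, 504 passed it and 13 turned sign. Per grid 1152 kept both, 66 newly passed, 146 no longer passed and 9 turned. Whole-array log2 ratios that turned were bacE at -0.017 per grid and lutC at -0.087 with a dye term. With 1 replicate left out lutC ran from -0.15 to 0.94, cgeB from -0.078 to 2.12, cgeA from -0.17 to 1.81, cgeC from -0.54 to 1.19, cotG from -0.49 to 1.55, bacA from -0.59 to 0.17, bacC from -0.019 to 0.96, sspH from -0.61 to 0.23, nasF from -0.73 to 0.075 and nasD from -0.77 to 0.081. Per-grid ratios that turned were cotV at -0.032 with plain subtraction, -0.0033 with scaling and -0.11 with replicates 1 and 3 as 1 culture, and bacE at 0.024 in the deposited table. With 1 replicate left out per-grid ratios ran from -0.42 to 0.24 for cotV, -0.16 to 0.14 for bacE, -0.98 to 0.13 for sigB, -0.29 to 0.012 for fhuG and -0.041 to 0.23 for bacC. The causes were not tested. Signal over background limits dim genes, since 3348 of 4106 passed the luc limit on 3 arrays.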

Other observations

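Genes called in the per-grid fit lay next to one another along the chromosome, in an analysis added after seeing the data. In locus tag order, 39 runs of at least 4 neighbouring genes were called the same way, 26 that rose and 13 that fell, with 219 genes in all. In 1000 shuffled orders the highest number of runs was 6, and it was 4 when genes were shuffled within their print grids. Shuffling single genes also breaks up operons, whose genes are transcribed together. More runs than in shuffled orders would thus be found for any calls that follow operons. Among the runs that rose, named after their values were seen, were narG, narH, narI, narJ and arfM of nitrate respiration (mean log2 ratio 0.66), resA to resE of cytochrome maturation and its regulators (0.76), the cell shape and division site genes mreB, mreC, mreD, minC and minD (0.91), the leucine genes leuA to leuD (0.88), the biotin genes bioD, bioFC, bioK and bioW (1.10) and the thiamine genes tenA to thiD with fabI (0.95). Runs that fell held spoVAB to spoVAF of spore dipicolinic acid uptake (-0.60), mmgA to mmgF (-0.83), the murein recycling genes from ybbC to murR (-0.98), the histidine genes from hisIE to hisZ (-0.82), pucJ to pucM with pucR of purine breakdown (-0.82) and yqjA with the arginine transport genes artP, artQ and artR (-0.98).

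Other lists did not pass with camera in either fit, though fry called phosphate limitation per grid (adjusted p = 0.0185). Per grid, competence had a median of 0.15, with 5 of 27 genes that rose. Motility had 0.15, with 2 of 46 that rose. Sporulation initiation had -0.19, with 4 of 24 that fell, spo0A, spoIIAA, spoIIAB and spoIIE, at log2 ratios of -0.50, -0.52, -0.71 and -0.84. Extracellular proteases and hydrolases had -0.05, with 4 of 23 that rose and 3 that fell, namely aprE, nprE and vpr at -2.20, -0.86 and -0.44. The citric acid cycle had 0.31, with odhA, odhB, sucD and fumC rising by 0.95, 0.81, 0.69 and 1.05, and citA, citB and citZ at -0.81, -1.32 and -0.79. Phosphate limitation had 0.12, with 5 of 19 that rose, the phosphate transport genes pstS, pstC, pstA and pstBB at 0.94, 0.71, 0.66 and 0.47 and tuaF at 0.61. Amino acid degradation had -0.05, CodY-repressed genes -0.14, heat shock chaperones -0.09, cysteine and methionine synthesis -0.0068 (mean 0.0020), multidrug export -0.03 and the PBSX prophage -0.01. The single genes in this paragraph were named after their values were seen.

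The tests of explanations below were chosen after the results were seen. With 1 loess per array 0 genes passed, and 793 did with a loess per print grid. A strain difference that follows the grids is argued against, since grid medians turned to TEK1 over PY79 correlated at r = -0.89 or lower between replicate 1 and the arrays of the other dye orientation. A dye balance that follows the print grid may account for some of the difference. With grid differences added in the self-test, 1 loess per array still recovered 98.0% of genes changed by 2. That simulation gave every gene the same noise SD and each grid a constant shift. It therefore cannot tell how much of the difference the dye balance accounts for. Unturned medians correlated at 0.89 or higher, which is the same result with its sign reversed and not a separate test. With 4 sign patterns of the arrays no share under 0.05 can be had: as many whole-array genes were called in 4 of the 4 patterns, 0 in each, though 1050 genes had an unadjusted p under 0.05 where the signs followed the dye, against 467. Per grid 793 genes were called in 1 pattern, with 0 as the highest other, and lists were called in 20 against 16 (whole-array, 1 pattern) and 15 against 19 (per-grid, 2 patterns), the 19 where the signs followed the dye.

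The lists of ribosomal proteins, of ATP synthase and respiration and of glycolysis were called up in TEK1, with adjusted p = 0.595 for each with an estimated correlation. Dye bias that depends on brightness stays open, because the dyes were exchanged on 1 array only. On that array the lowest of the 3 list medians was 0.63 per grid (SD 0.15 over the arrays) and 0.24 with 1 loess per array (SD 0.68), both for glycolysis. An earlier growth state of TEK1 at sampling may account for it and stays open too, since 4 of 10 lists of functions used after exponential growth had a median below 0, and no growth curve was used here. An effect of the yvfI mutation itself is also open and untested.

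The forespore list was called down in TEK1, with adjusted p = 0.595 with an estimated correlation. Its whole-array call ended without replicate 1 (median -0.11, adjusted p = 0.0558). A smaller share of sporulating cells is argued against as the whole cause, though not excluded. The late mother-cell median lay above the forespore median by 0.91, 0.58 and 0.66 on replicates 1 to 3 (SD 0.17), lowest 0.58. Both list medians were known when this comparison was chosen, so it is not independent evidence. The late mother-cell median itself was 0.73, -0.0050 and 0.0090 on these arrays, so its rise rested on replicate 1. Sporulation initiation genes went with a smaller share, as 4 of 24 fell per grid and 0 rose. That list did not pass (median -0.19, camera adjusted p = 0.172). The late and forespore lists cover different stages, so the gap between them does not settle the share of sporulating cells. The forespore median was -0.39 with a dye term, but dye bias stays open because 1 of the 2 orientations is replicate 1 alone, with a median of -0.18 against -0.59 and -0.65 on replicates 2 and 3. An effect of yvfI on forespore genes is a hypothesis that these arrays cannot separate from dye bias or from other differences between the strains.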
